A study of Mus musculus with 14 samples.

How the data were processed

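RNA was measured in purified mouse hepatocytes by sequencing of stranded, polyA-selected libraries, per the labels. The 14 libraries fall into 6 groups. At postnatal day 10 (P10) and at 1 month of age there were 2 libraries each from hepatocyte knockout (HKO) animals, which carry floxed Srsf1 and an albumin-Cre transgene, and 2 each from albumin-Cre controls. In the acute model, floxed animals received an AAV8 vector with the hepatocyte TBG promoter at 8 weeks and were sampled 2 weeks later, at 10 weeks; 3 libraries came from animals given iCre and 3 from animals given GFP. The labels do not say that replicates are separate animals. The HKO controls are described by albumin-Cre alone, while both acute groups are floxed animals. Differences between the floxed line and the control line are therefore not separated from the knockout at P10 and 1 month. In the acute model only the knockouts received iCre, so effects of iCre itself are not separated from the loss of Srsf1.

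The authors deposited 1 table of transcript abundances in TPM, a share of all transcripts in a library corrected for transcript length, for all 14 libraries. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17.1.14 and kallisto 0.46.0 against the mouse build GRCm38 (mm10), and DESeq2 was used with no version given. The authors also deposited 3 gene tables, 1 per knockout comparison. Per the file headers these hold a mean normalized count, a log2 fold change with its standard error, the score of the authors' test, and a p-value with its adjusted p-value; how transcript estimates became gene counts is not given in the sources used here. The TPM table held 137767 transcripts of 54446 genes, and each library summed to between 999999.6 and 1000000.24 TPM. All sample columns were used, and 53229 gene identifiers matched the GENCODE M21 annotation of GRCm38 in both identifier and version.

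TPM keep no sequencing depth, so the depth of each library is unknown and no count model was fitted. The mean normalized counts in the deposited tables summed to 105226010 at P10, 108247108 at 1 month and 119476488 in the acute comparison, which are totals over an average library and not depths of single libraries.

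Gene TPM were sums over a gene's transcripts. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(TPM + 1), for genes with a mean of at least 1 TPM over the libraries in the fit. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The P10 and 1 month comparisons shared a fit of 8 libraries with 4 residual degrees of freedom, the acute comparison used its own 6 libraries with 4, and the difference between the acute and 1 month effects used all 14 with 8. TPM are shares of a total, so the median gene moved with the composition of each library: the median log2 fold change of all genes was 0.25 at P10, -0.001 at 1 month and -0.36 in the acute comparison. Fold changes of single genes are therefore given relative to that median unless stated otherwise, while adjusted p-values are those of the fit to the deposited TPM.

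Fixed before the data were examined were 52 gene lists, of pathways and of markers of other cell types. Lists with at least 5 tested members were compared with all other genes by limma's camera test with a preset correlation of 0.01, and adjusted over the lists. The members of each list were also counted by the gene test, adjusted over all genes and adjusted over the list alone. Transcript usage was tested with limma's diffSplice (F test per gene, adjusted over genes) on transcripts with a mean of at least 1 TPM and at least 5% of their gene's mean TPM, in genes with at least 2 such transcripts. A gene counted as changed in usage when its adjusted p passed 0.05 and the share of 1 transcript differed by at least 10 percentage points between group means. TPM were quantified on annotated transcripts, so other isoforms are not seen. Usage calls within the 3 splicing lists, and calls shared between comparisons, were set against all other tested genes with one-sided Fisher tests, added after the data were seen for the lists. Shares of TPM were compared between groups with exact permutation tests, two-sided.

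The genes named in the text follow a rule set before the data were examined: Srsf1 and the other SR proteins, the 8 largest rises and 8 largest falls per comparison among genes that passed with a mean of at least 5 TPM and no overlap between the groups, up to 3 members of each described list with the smallest p, and members that moved against their list. For differences between comparisons the 5 largest each way are named, and for transcript usage genes among the 6 with the largest change of share. Predicted genes and pseudogenes were left out of these names. Genes with near-identical copies, such as the Mup, Cyp2c, Sult2a, Gsta, Gstm and Saa families and ribosomal protein genes, are uncertain singly because reads can be split between copies.

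The gene, list and usage tests were first run on simulated data made from the libraries' means and spread. For the gene and usage tests, 100 genes were changed by a log2 of 1 and 100 by a log2 of 2. The gene test recovered 51 and 89 of these at P10, 39 and 85 at 1 month, and 66 and 94 in the acute design, with 10, 6 and 6 false calls. For transcript usage, a log2 change of 2 in 1 transcript was recovered in 51, 60 and 75 of 100 genes. A log2 change of 1 was recovered in 17, 13 and 38, and there were 12, 11 and 8 false calls. The usage simulation set no minimum share difference. For the list test 1 list of 26 genes was shifted, with genes simulated independently of each other. That list passed in each design, with 0 other lists called.

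Alternatives changed the pseudocount to 0.1, the filter to none or to at least 5 TPM, the scaling (median-ratio, quantile, and rescaling without mitochondrially encoded genes and the 20 most abundant genes), the variance model, the libraries in the fit, and the list test (camera with an estimated correlation, and fry). Further ones added a minimum log2 fold change of 1, took calls from the authors' deposited tables, used the replicate number as a block, and left out each library in turn. Rescaling over nuclear-encoded protein-coding genes, rescaling without mitochondrially encoded genes alone, and separate usage fits of the 4 libraries of each age were added after the data were seen.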

Results

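RNA abundance was measured in hepatocytes of C57BL/6 mice that had lost the splicing factor SRSF1 by either of 2 routes. In the HKO model the albumin-Cre transgene deletes Srsf1 as the liver develops, and there were 2 knockout and 2 control libraries at P10 and the same numbers at 1 month. In the acute model a virus delivered the recombinase to adult hepatocytes, with 3 knockout libraries (acute HKO) and 3 GFP controls. The values are TPM, and the depth of each library is unknown. Correlations between libraries of the same group, across genes on the log2 scale, ranged from 0.976 to 0.994.

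The targeted gene was examined first. Srsf1 (ENSMUSG00000018379.17, chromosome 11, 88047373 to 88053755, plus strand, GRCm38) was lower in every knockout library than in every control library of the same comparison. At P10 it measured 43.6 and 46.4 TPM in the controls and 30.0 and 23.4 TPM in the HKO libraries. At 1 month it measured 23.2 and 20.01 TPM in the controls and 7.74 and 9.17 TPM in the HKO libraries. In the acute model it measured 16.5, 29.7 and 32.3 TPM with GFP and 3.69, 5.34 and 4.16 TPM with iCre. The knockout means were 59.3% of the control mean at P10, 39.2% at 1 month and 16.8% in the acute model. On the deposited TPM the P10 difference did not pass the threshold (log2 fold change -0.74, or -0.99 relative to the median gene, SE 0.23, limma adjusted p = 0.05451), and it passed after median-ratio rescaling (-1.01, adjusted p = 0.007508). Srsf1 fell at 1 month (relative log2 fold change -1.26, SE 0.23, adjusted p = 0.006101) and in the acute model (-1.93, SE 0.24, adjusted p = 2.767e-06). In the authors' deposited tables its log2 fold changes were -1.07, -1.43 and -2.23, with adjusted p of 6.324e-12, 5.348e-08 and 5.536e-21. Which exons are deleted is not given in the sources used here, so transcripts that still include Srsf1 sequence after deletion are counted as well.

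**Figure D1:**
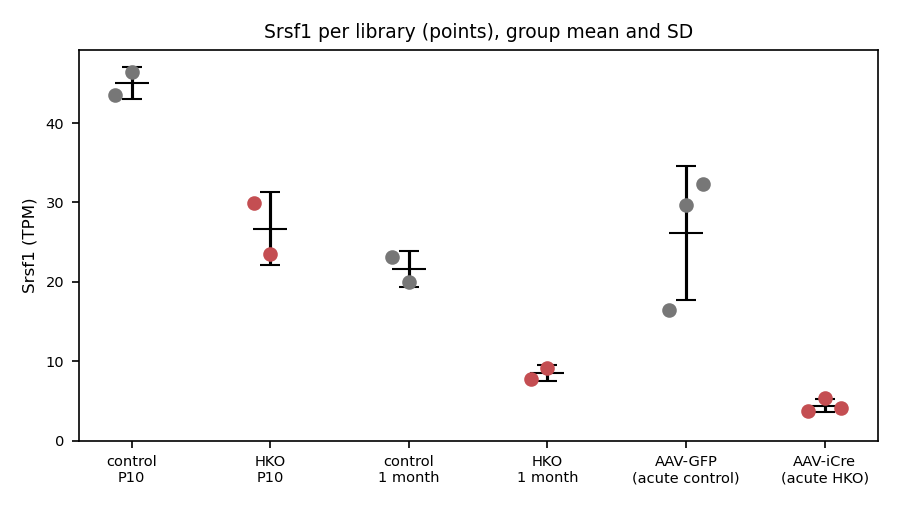
Srsf1 in TPM (y axis, from 0) in each library (points), by group (x axis), with the group mean and SD as bars; controls are grey and knockouts red. The acute knockout libraries sit between 3.69 and 5.34 TPM, and their GFP controls between 16.5 and 32.3 TPM.

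Other SR proteins were compared in the same way, since members of this family regulate splicing alongside SRSF1. None of the 12 tested passed at P10, and Srsf1 alone passed at 1 month. After median-ratio rescaling Srsf1 alone passed at P10, while Srsf4 (-0.52, adjusted p = 0.03603) and Tra2a (-0.41, adjusted p = 0.04654) were lower beside Srsf1 at 1 month. The authors' deposited table for P10 also has Srsf9 (0.42, adjusted p = 0.01066), Srsf4 (0.42, adjusted p = 0.01816) and Srsf10 (0.34, adjusted p = 0.04295) as higher. In the acute model 8 fell, Srsf1 included, and 1 rose. Srsf4 rose from 13.1 ± 1.42 to 21.6 ± 1.18 TPM (SD, n = 3; relative log2 fold change 1.05, SE 0.19, limma adjusted p = 0.0093), and Srsf2 fell (-0.70, SE 0.22, adjusted p = 0.001385). Srsf10 fell by less (-0.31, adjusted p = 0.01638). Tra2a (-0.54), Tra2b (-0.35), Srsf5 (-0.33), Srsf6 (-0.32) and Srsf7 (-0.24) passed on the deposited TPM and not after median-ratio rescaling, under which Srsf11 passed as higher (0.69, adjusted p = 0.01187). Of the 8 lower SR proteins 3 passed without GFP_acute replicate 2, 4 without GFP_acute replicate 3 and 5 without acHKO_acute replicate 3, and Srsf4 did not pass without GFP_acute replicate 2.

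The first comparison asked what loss of SRSF1 changes in hepatocytes of pups at P10. Hamp, which encodes the iron-regulating hormone hepcidin, rose most, from 2.13 ± 0.387 to 936.5 ± 271.2 TPM (SD, n = 2; relative log2 fold change 7.95, SE 0.35, limma adjusted p = 2.019e-07). The ubiquitin-like gene Ubd (5.18), the protease inhibitor Slpi (5.14), the trefoil peptide Tff3 (4.63), Ly6d (4.41), the glutathione transferase Gstm3 (4.40), Sprr1a (4.25) and Ifi27l2b (4.01) rose as well. The secreted peptide gene Prok1 fell most, from 33.4 ± 2.04 to 1.18 ± 0.739 TPM (-4.27, SE 0.22, adjusted p = 1.176e-06). Sult2a2 (-4.03), Cyp2c69 (-3.56), Rpl29 (-3.36), the mitochondrial tRNA mt-Tp (-2.76), the esterase Ces3a (-2.74), Sult2a1 (-2.72) and Sult2a5 (-2.62) also fell. Sult2a2, Cyp2c69 and the other Sult2a genes have near-identical copies.

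Lists of genes that mark the mature hepatocyte's output were examined at P10, and most of their members did not pass. Of 30 hepatocyte secreted plasma proteins 5 fell and none rose (1 higher and 8 lower adjusted over the list alone), among them the thyroxine carrier Ttr (relative log2 fold change -1.47, SE 0.20), Itih1 (-1.59) and Fgg (-1.10); camera gave an adjusted p of 4.598e-13, and an adjusted p of 0.7504 with an estimated correlation. After median-ratio rescaling 20 of them were lower, while without either control library or without HKO_P10 replicate 2 the count was 1. Of 30 cytochrome P450 and drug metabolism genes 7 fell and 2 rose (3 higher and 9 lower adjusted over the list alone; camera adjusted p = 3.151e-09, and 0.7504 as the adjusted p with an estimated correlation). Ces3a and Ugt2a3 (-2.31) fell, and Gstm1 (1.80) and Cyp2a5 (2.46) rose against the list. The lower count was 14 after median-ratio rescaling, 3 without control_P10 replicate 1, and 4 without control_P10 replicate 2 or HKO_P10 replicate 2. Tdo2 (-1.65) and Sds (-2.10) were the 2 of 28 genes of the urea cycle and amino acid breakdown that fell (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 2.432e-07, estimated correlation adjusted p = 0.7504). That count was 11 after median-ratio rescaling, 0 without control_P10 replicate 1, and 1 without control_P10 replicate 2 or HKO_P10 replicate 1.

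Of 18 female-biased liver genes 8 fell and 1 rose at P10 (2 higher and 10 lower adjusted over the list alone; camera adjusted p = 2.168e-10, estimated correlation adjusted p = 0.7504). Hao2 (relative log2 fold change -2.06, SE 0.22), Sult2a2 and Cyp2b13 (-1.52) fell, and Atp6v0d2 (0.89) rose against them on the deposited TPM and not after median-ratio rescaling. One of the HKO libraries, HKO_P10 replicate 2, held 74.7 TPM of Xist and 0.144 TPM summed over Y-linked genes. The other 13 libraries held at most 0.0147 TPM of Xist and between 24.9 and 68.0 TPM of Y-linked genes. By these RNAs the P10 knockout group mixes a female with a male sample while both P10 controls are male. Sex and knockout are therefore partly confounded at P10, above all for sex-biased genes. As mean log2(TPM + 1) the female-biased genes measured 4.88 in both P10 controls, 4.10 in HKO_P10 replicate 1 and 3.60 in HKO_P10 replicate 2. The mean was thus lowest in the female library, opposite to a female-biased rise. Without that library 5 of the female-biased genes fell. Atp6v0d2 did not pass without control_P10 replicate 2 or HKO_P10 replicate 1.

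Genes of stress responses rose at P10. Of 24 NRF2 targets and glutathione genes 19 rose and none fell (20 and 0 adjusted over the list alone; camera adjusted p = 3.151e-09, estimated correlation adjusted p = 0.7504), with Gstm3, Gsta1 (relative log2 fold change 2.95, SE 0.27) and Ugdh (2.50) as examples. Between 10 and 11 rose without either control library or HKO_P10 replicate 1. Of 28 integrated stress and unfolded protein response genes 13 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 4.502e-06, estimated correlation adjusted p = 0.7504), including Trib3 (3.27), Nupr1 (2.60) and the transcription factor Atf3 (2.172). Of 31 p53 targets 20 rose and none fell (20 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.934e-05, estimated correlation adjusted p = 0.8083), including Phlda3 (1.81), Ddit4l (1.31) and Pmaip1 (1.10). The p53 target count was 13 after median-ratio rescaling, with 2 lower, 9 without control_P10 replicate 1 or HKO_P10 replicate 2, and 12 without control_P10 replicate 2. Immediate early genes, which can rise with handling or dissociation of cells, were higher too: 7 of 17 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.001018, estimated correlation adjusted p = 0.7504). That count was 4 after median-ratio rescaling, and 4 without either control library or HKO_P10 replicate 2.

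Antigen presentation, ductular and cell cycle genes were compared at P10, and part of each group rose on the deposited TPM. Of 14 antigen presentation genes 8 rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 3.749e-06, estimated correlation adjusted p = 0.7504): Cd74 (relative log2 fold change 2.66, SE 0.30), H2-Ab1 (1.73) and H2-DMb1 (1.30) were the most significant. Of 11 cholangiocyte and ductular markers 6 rose (8 adjusted over the list alone; camera adjusted p = 5.675e-05, estimated correlation adjusted p = 0.4659), including the claudins Cldn4 (3.25) and Cldn7 (2.82) and Bicc1 (1.31). After median-ratio rescaling 4 of these rose and 1 fell. Of 26 cell cycle genes 14 rose on the deposited TPM (23 adjusted over the list alone; camera adjusted p = 9.842e-06, estimated correlation adjusted p = 0.7591), by small amounts such as 0.62 for Plk1, 0.57 for Aurka and 0.48 for Cdca8. That count was 2 after median-ratio rescaling, 2 without HKO_P10 replicate 1, and 0 without HKO_P10 replicate 2 or either control library.

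Markers of further cell types were compared at P10. Of 22 macrophage and Kupffer cell markers 8 rose (10 adjusted over the list alone, 4 after median-ratio rescaling and 4 without HKO_P10 replicate 1; camera adjusted p = 0.005345, estimated correlation adjusted p = 0.8083), with Cd9 (relative log2 fold change 2.13), Cd14 (2.05) and Ccr2 (1.30) as examples. The macrophage list did not pass camera after median-ratio rescaling, over coding genes, without mitochondrially encoded genes in the scaling, or without HKO_P10 replicate 1. None of 19 endothelial markers passed. Among 13 stellate cell and fibroblast markers Col1a1 (0.90), Rgs5 (0.56) and Lum (0.51) rose and Cxcl12 (-1.29) fell (camera adjusted p = 0.9221); 1 rose after median-ratio rescaling, 1 rose without either control library or HKO_P10 replicate 1, and none fell without either control library or HKO_P10 replicate 2. Hbb-bs (1.95) rose among 12 erythroid markers, 7 of which were higher adjusted over the list alone. Without HKO_P10 replicate 1, which leaves HKO_P10 replicate 2 as the lone knockout, 9 erythroid, 7 neutrophil and 3 platelet markers were higher. Without HKO_P10 replicate 2 no erythroid or platelet marker was higher. Hba-a1 measured 582.8 TPM in HKO_P10 replicate 2 and between 45.6 and 95.5 TPM in the other P10 libraries. Lcn2 (2.89) was the neutrophil marker that rose of 8 tested, and Clec1b (0.88) the platelet marker of 6. Lcn2 is on the list of acute phase genes as well, so its rise does not single out neutrophils. No T and NK cell or mesothelial marker, 2 B and plasma cell markers and 1 pancreatic acinar marker reached the TPM minimum, and none passed.

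In all, 1488 of 11736 genes changed at P10, 1268 higher and 220 lower, so that 14.8% were lower. The direction depended on the scaling: after median-ratio rescaling 715 were higher and 699 lower (49.4%), without mitochondrially encoded genes 3103 and 479 (13.4%), and over coding genes 4164 and 435 (9.5%). No gene called on both the deposited and the median-ratio scale changed direction, though a rescaling that shifts all genes nearly alike leaves little room for this. Without control_P10 replicate 1 or 2 the count was 562 or 613, and without HKO_P10 replicate 1 or 2 it was 896 or 701. The authors' deposited table held 4845 genes past the same threshold, and of 1450 limma calls listed there 1369 were called in the same direction. With camera 25 of 47 lists changed, 13 higher and 12 lower; with an estimated correlation 0 changed (2 at an unadjusted p under 0.05), and fry called 13.

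The same question was put at 1 month, when hepatocytes of control animals have largely stopped dividing. All 26 tested cell cycle genes rose (26 adjusted over the list alone and after median-ratio rescaling; camera adjusted p = 6.051e-35, estimated correlation adjusted p = 0.2374). The cyclin Ccnb2 rose from 0.365 ± 0.0802 to 8.52 ± 0.594 TPM (SD, n = 2; relative log2 fold change 2.80, SE 0.19, limma adjusted p = 7.699e-06), and Kif20a (2.10) and Hmmr (2.06) rose with it. The largest rise was that of Ly6d, from 0.512 ± 0.0688 to 66.8 ± 3.95 TPM (5.49, SE 0.20, adjusted p = 2.321e-07). Next came the imprinted fetal RNA H19 (4.75, SE 0.44; 37.2 ± 29.3 against 0.192 ± 0.0788 TPM), Gstm3 (4.69), Gsta1 (4.57), Cyp3a41a (3.76), Tff3 (3.64), the osteopontin gene Spp1 (3.62) and Nupr1 (3.54).

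Among the largest falls at 1 month, Mup7 (relative log2 fold change -4.71, SE 0.79) and Mup11 (-3.93, SE 0.36; 300.0 ± 20.5 against 4579 ± 50.1 TPM) encode major urinary proteins, as does Mup12 (-3.22), and have near-identical copies. Rgs16 (-3.61), the phosphatidate phosphatase Lpin1 (-3.60), the glucocorticoid-induced gene Fkbp5 (-3.07), Saa4 (-3.05) and the uridine phosphorylase Upp2 (-3.005) fell too. Clock genes differed between the same libraries (below), and the time of day at sampling is not known. Falls of genes with a daily rhythm therefore cannot be assigned to the knockout alone.

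Of 16 fetal liver and oncofetal genes 6 rose and none fell (8 and 0 adjusted over the list alone; camera adjusted p = 4.567e-08, estimated correlation adjusted p = 0.1573), including Ly6d, H19 and the lipase Lpl (relative log2 fold change 2.84). Of 24 NRF2 targets and glutathione genes 8 rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 1.735e-08, estimated correlation adjusted p = 0.5916), with Gstm2 (2.68) beside Gsta1 and Gstm3. Acute phase genes went the other way: 15 of 26 fell and none rose (1 higher and 19 lower adjusted over the list alone; camera adjusted p = 5.182e-15, estimated correlation adjusted p = 0.235), including the metallothioneins Mt2 (-2.84) and Mt1 (-2.29). The acute phase count was 9 without HKO_1m replicate 1.

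Metabolic, ribosomal and clock gene lists were compared at 1 month, and the metabolic lists did not all move the same way. Of 28 genes of the urea cycle and amino acid breakdown 6 fell and none rose (0 and 12 adjusted over the list alone; camera adjusted p = 2.38e-07, estimated correlation adjusted p = 0.6992), including Asl (relative log2 fold change -1.41), Tdo2 (-1.06) and Arg1 (-1.03). Without control_1m replicate 2 or HKO_1m replicate 1 this count was 0, without HKO_1m replicate 2 it was 11, after median-ratio rescaling it was 11, and the list did not pass camera under quantile normalization. Among 30 hepatocyte secreted plasma proteins F7 (-0.97) and Rbp4 (-0.83) fell (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 5.884e-07, estimated correlation adjusted p = 0.6992). After median-ratio rescaling 14 were lower, while under quantile normalization the list as a whole went up without passing. The plasma protein count was 0 without either control, 1 without HKO_1m replicate 1 and 6 without HKO_1m replicate 2. Cholesterol synthesis and uptake genes went up as a list, with 3 of 24 higher and none lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.001135, estimated correlation adjusted p = 0.6992). Fatty acid oxidation and ketogenesis genes did too, with 3 of 30 higher and none lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.03961, estimated correlation adjusted p = 0.7885). The cholesterol count was 7 after median-ratio rescaling, with 1 lower, and 6 without HKO_1m replicate 1, and the fatty acid list did not pass camera without control_1m replicate 1 or either HKO library, nor over coding genes or without mitochondrially encoded genes in the scaling. None of 42 cytosolic ribosomal protein genes passed, yet as a list they were lower (median -0.56, camera adjusted p = 5.711e-10, estimated correlation adjusted p = 0.6992), with 25 lower after median-ratio rescaling and 29 lower without HKO_1m replicate 2. Of 16 circadian clock genes 7 fell and 1 rose (1 and 10 adjusted over the list alone; camera adjusted p = 8.491e-06, estimated correlation adjusted p = 0.5431): Ciart (-2.51), Tef (-2.08) and Nr1d1 (-1.47) fell, and Arntl (1.13), which acts in opposite phase to them, rose. Ciart measured 18.9 ± 14.6 TPM and Tef 59.0 ± 34.6 TPM in the control libraries (SD, n = 2), and 4 clock genes fell without control_1m replicate 1 or either HKO library. The time of day at sampling is not given in the sources used here.

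Markers of other cells were compared at 1 month. Macrophage markers rose most widely and differed between the HKO libraries. Of 22 macrophage and Kupffer cell markers 14 rose and none fell (19 and 0 adjusted over the list alone; camera adjusted p = 4.767e-14, estimated correlation adjusted p = 0.5431), including Cd68 (relative log2 fold change 2.34), Lyz2 (2.31) and Marco (2.22). The macrophage count was 7 after median-ratio rescaling, 6 without control_1m replicate 1, and 7 without HKO_1m replicate 1. Lyz2 measured 25.9 TPM in HKO_1m replicate 1, 7.44 TPM in HKO_1m replicate 2, and 1.96 and 2.11 TPM in the controls. Of 19 endothelial markers Fcgr2b (1.56) rose (camera adjusted p = 2.582e-06, estimated correlation adjusted p = 0.6992). None of these endothelial markers passed after median-ratio rescaling or without control_1m replicate 2, and 18 did without HKO_1m replicate 2. The endothelial and stellate lists did not pass camera without HKO_1m replicate 1 or when mitochondrially encoded genes were left out of the scaling, nor over coding genes, and the stellate list did not pass under quantile normalization. Of 13 stellate cell and fibroblast markers 3 rose, Rgs5 (1.31), Col3a1 (1.27) and Vim (1.27; camera adjusted p = 5.569e-04, estimated correlation adjusted p = 0.6992), while 2 rose and 1 fell after median-ratio rescaling and 8 rose without HKO_1m replicate 2. Of 11 cholangiocyte and ductular markers Spp1, Anxa3 (0.83) and Bicc1 (0.64) rose (camera adjusted p = 0.001613, estimated correlation adjusted p = 0.2374), and 1 rose without either control library. Lcn2 (-1.07) fell among 8 neutrophil markers, though not without either control or HKO_1m replicate 1. Lcn2 is also on the acute phase list. No platelet, erythroid or B cell marker passed, and no T and NK cell or mesothelial marker reached the TPM minimum. On the log2(TPM + 1) scale 1 pancreatic acinar marker measured 3.36 and 3.52 in the controls, and 2.21 and 2.58 in the HKO libraries.

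**Figure D2:**
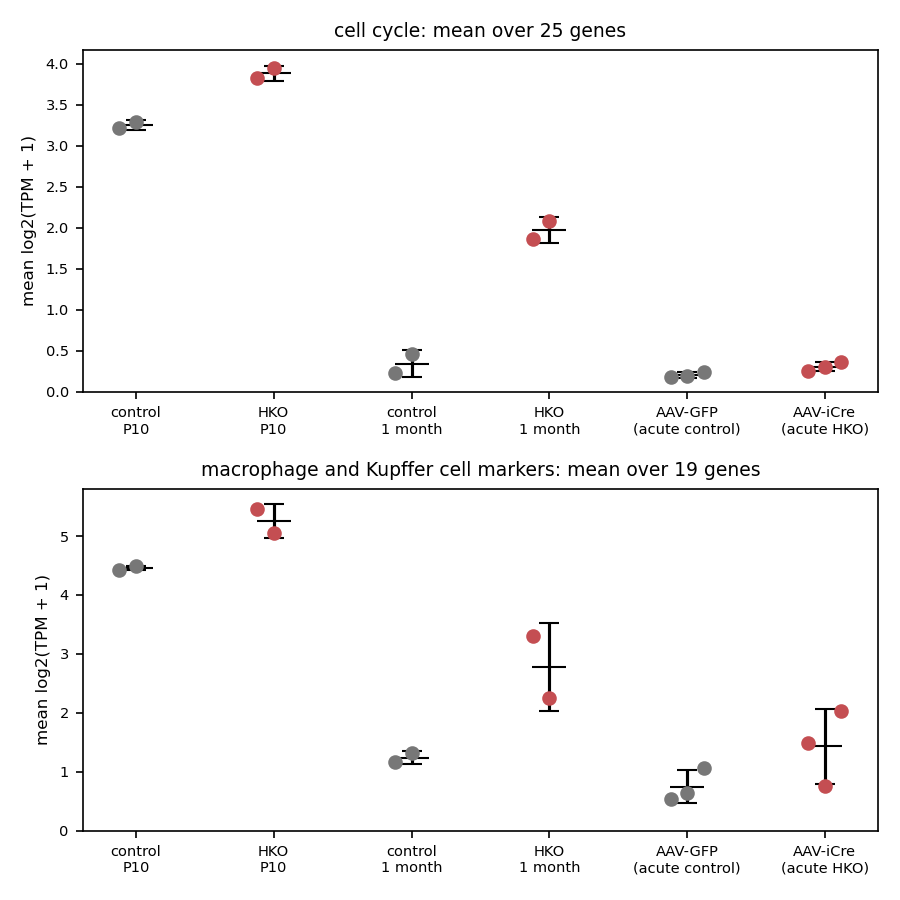
Mean log2(TPM + 1) per library (points) over cell cycle genes (upper panel) and macrophage and Kupffer cell markers (lower panel), by group (x axis), with the group mean and SD as bars; controls are grey and knockouts red. At 1 month both HKO libraries lie above both controls in both panels.

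At 1 month 805 of 11736 genes changed, 572 higher and 233 lower (28.9% lower). After median-ratio rescaling 785 were higher and 902 lower (53.5%), without mitochondrially encoded genes 2601 and 255 (8.9%), and over coding genes 3814 and 293 (7.1%). Without HKO_1m replicate 2 the count was 1344. The authors' deposited table held 2454 genes past the threshold, and 746 of the 785 limma calls listed there were called in the same direction. With camera 36 of 47 lists changed, 21 higher and 15 lower; with an estimated correlation 0 changed (5 at an unadjusted p under 0.05), and fry called 5. Without HKO_1m replicate 1 camera called 22 lists.

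The effect of age on the HKO response was tested directly, as the HKO effect at 1 month minus that at P10. It differed for 329 genes, 118 more positive and 211 more negative at 1 month (268 and 262 after median-ratio rescaling). For 9 of 26 cell cycle genes the effect was more positive at 1 month and for none more negative (17 and 0 adjusted over the list alone; camera adjusted p = 7.31e-28, estimated correlation adjusted p = 0.5067), with 18 after median-ratio rescaling. Of 18 female-biased genes 6 were more positive (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.123e-13, estimated correlation adjusted p = 0.5123). Of 26 acute phase genes 11 were more negative and 1 more positive (1 and 14 adjusted over the list alone; camera adjusted p = 3.997e-08, estimated correlation adjusted p = 0.5067). The P10 side of this difference carries the mixed sex of its HKO group, so for sex-biased genes age and sex are not fully separated. Hamp, which rose at P10, measured 613.1 TPM in HKO and 682.9 TPM in control libraries at 1 month. Across the 11736 genes the fold changes at the 2 ages had Pearson's r = 0.382 and Spearman's rho = 0.346, over genes that are not independent replicates. Both ages called 309 genes higher (61.8 would be shared by independent lists), 41 lower (4.4) and 25 in opposite directions (35.9). Without control_P10 replicate 1 or 2 the count of 329 was 203 or 207, and without HKO_1m replicate 2 it was 1688.

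The acute comparison asked what follows within 2 weeks of deleting Srsf1 in adult hepatocytes. Its controls received GFP and no iCre, so the changes below cannot be divided between the deletion and iCre itself. Gstm3 rose most, from 28.0 ± 2.24 to 668.2 ± 167.1 TPM (SD, n = 3; relative log2 fold change 4.86, SE 0.22, limma adjusted p = 9.518e-10). The drug-inducible cytochrome Cyp2b10 (4.59, SE 0.71), Cib3 (4.41), the stress-induced mTOR inhibitor Ddit4 (3.86), the lectin Lgals1 (3.61), Gsta1 (3.52), Gstp3 (3.50) and the water channel Aqp8 (3.33) followed. Cyp2c67 fell most, from 341.6 ± 187.0 to 14.7 ± 13.6 TPM (-4.33, SE 0.44, adjusted p = 1.028e-06). Mup15 (-4.08, SE 0.92; adjusted p = 0.06258 after median-ratio rescaling), the secreted protein gene Fgl1 (-3.90), Cyp2c68 (-3.88), Saa4 (-3.65), Ugt2b1 (-3.64), Saa1 (-3.40) and the prolactin receptor gene Prlr (-3.18) fell as well. Cyp2c, Mup and Saa genes have near-identical copies.

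Mitochondrially encoded mRNAs took up more of the acute knockout libraries. Of 13 such genes 12 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.991e-16, estimated correlation adjusted p = 0.851), with relative log2 fold changes of 2.11 for mt-Nd4 (SE 0.26), 2.05 for mt-Atp6 and 1.89 for mt-Nd5. Together they made up 37.3 ± 4.88% of TPM in the knockouts and 14.1 ± 2.28% in the GFP controls (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 can give). At P10 the shares were 30.5 ± 4.55% and 29.6 ± 2.42%, and at 1 month 42.9 ± 10.4% and 28.3 ± 3.55% (SD, n = 2; exact permutation p = 1 and 0.3333, of which the smallest possible is 0.333).

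**Figure D3:**
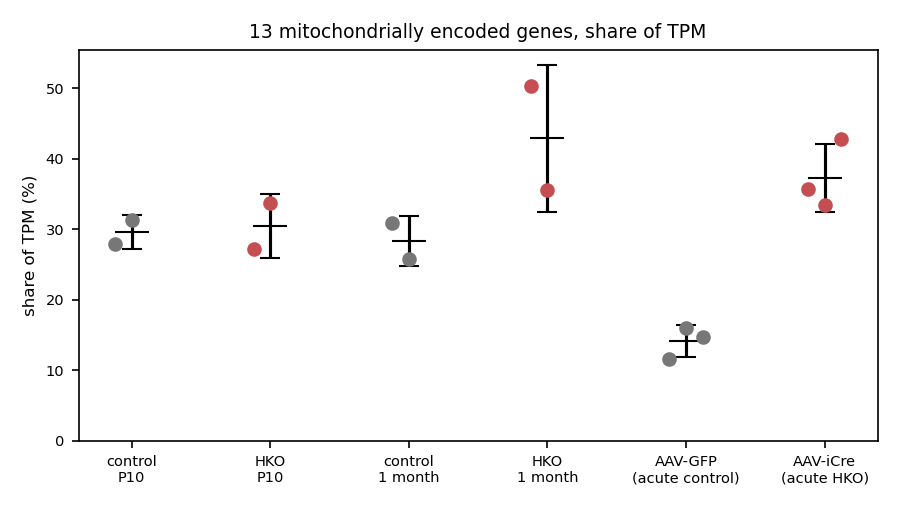
Share of TPM in percent (y axis, from 0) of the 13 mitochondrially encoded mRNAs in each library (points), by group (x axis), with the group mean and SD as bars; controls are grey and knockouts red. The acute knockout libraries lie between 33.4% and 42.8%, and their GFP controls between 11.6% and 16%.

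Nuclear genes for translation and secretion fell in the acute knockout. Of 42 cytosolic ribosomal protein genes 35 fell and none rose (0 and 40 adjusted over the list alone; camera adjusted p = 4.92e-06, estimated correlation adjusted p = 0.9358), including Rpl24 (relative log2 fold change -0.85, SE 0.21), Rpl13a (-0.83) and Rpl6 (-0.81). After median-ratio rescaling 24 fell and 1 rose, without mitochondrially encoded genes 9 fell, and over coding genes 2 fell. Of 30 hepatocyte secreted plasma proteins 19 fell and none rose (0 and 21 adjusted over the list alone; camera adjusted p = 9.364e-04, estimated correlation adjusted p = 0.9358). The complement gene C9 (-2.22), the plasminogen gene Plg (-2.15) and the clotting factor gene F7 (-1.30) were among those that fell. The plasma protein count was 14 after median-ratio rescaling, with none higher, 9 lower over coding genes with 1 higher, and 12 without GFP_acute replicate 3, and the list did not pass camera under quantile normalization.

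Stress and lipid storage lists were compared in the acute knockout, where a minority of their genes rose. Of 22 NRF2 targets and glutathione genes 6 rose and 2 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.92e-06, estimated correlation adjusted p = 0.851): Gstm3, Gstm2 (relative log2 fold change 3.19) and Gsta2 (2.83) rose, and Mgst1 (-0.27) and Taldo1 (-0.17) fell on the deposited TPM and not after median-ratio rescaling, under which 10 rose and none fell. Neither fell without GFP_acute replicate 2 or 3 or acHKO_acute replicate 1 or 3. Taldo1 was higher by 0.06, without passing, when TPM were rescaled over coding genes. Of 24 p53 targets 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 1.265e-04, estimated correlation adjusted p = 0.851). The cell cycle inhibitor Cdkn1a (2.65), the stress hormone gene Gdf15 (2.36) and Btg2 (1.94) rose, against Fas (-0.44) and Gpx1 (-0.43). After median-ratio rescaling 10 p53 targets were higher and 1 lower, and without GFP_acute replicate 2 the lower count was 1. Of 14 lipid droplet and lipid uptake genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.001099, estimated correlation adjusted p = 0.851). The lipid droplet protein gene Cidec (2.51), the fatty acid transporter gene Cd36 (1.63) and Fitm1 (1.41) rose, while Lipc (-0.60), Fabp1 (-0.41) and Fitm2 (-0.23) fell; of these 3, Lipc alone passed after median-ratio rescaling, and 1 passed without acHKO_acute replicate 1.

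Markers of non-hepatocytes were compared in the acute libraries. Of 11 macrophage and Kupffer cell markers 8 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.633e-07, estimated correlation adjusted p = 0.851), including Clec4f (relative log2 fold change 1.34), C1qb (1.28) and Tyrobp (1.16). The macrophage count was 1 after median-ratio rescaling and 1 without acHKO_acute replicate 3 or GFP_acute replicate 1 or 3. Lyz2 measured 3.26, 1.11 and 6.20 TPM in the knockouts and 0.785, 0.992 and 1.80 TPM in the controls. Cd74 (1.61) and H2-Aa (1.21) rose among 10 antigen presentation genes (1 adjusted over the list alone; camera adjusted p = 0.005912, estimated correlation adjusted p = 0.851), and none of the 10 rose without acHKO_acute replicate 3 or GFP_acute replicate 1, the list failing camera in the former case. Plvap (1.24) rose among 10 endothelial markers (0 adjusted over the list alone; camera adjusted p = 1.056e-05, estimated correlation adjusted p = 0.851). The endothelial count was 0 without GFP_acute replicate 1 or acHKO_acute replicate 3, 2 without GFP_acute replicate 3, 4 without acHKO_acute replicate 2 and 7 without acHKO_acute replicate 1, and without acHKO_acute replicate 3 the 4 markers left were too few for the list test. Of 9 extracellular matrix and fibrosis genes 3 rose, among them Dcn (1.67) and Sparc (1.28), and Fn1 (-0.48) fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.02974, estimated correlation adjusted p = 0.851). No matrix gene rose without GFP_acute replicate 1, and the list did not pass camera after median-ratio rescaling, under quantile normalization, without mitochondrially encoded genes in the scaling, or without GFP_acute replicate 3 or acHKO_acute replicate 3. Among ductular markers Dsg2 (-0.22) fell of 5 tested, though not after median-ratio rescaling or without GFP_acute replicate 3, acHKO_acute replicate 2 or acHKO_acute replicate 3. Fewer than 5 markers of stellate, B, neutrophil, erythroid or acinar cells were tested, too few for a list test, and none of T and NK cells, platelets or mesothelium. Of 3 stellate markers 2 rose and 1 fell, the 1 B cell marker rose, 2 of 3 erythroid markers fell, 1 of 2 acinar markers rose and the other fell, and the 1 neutrophil marker did not pass. After median-ratio rescaling no stellate marker rose and 1 erythroid marker fell. No stellate marker rose without GFP_acute replicate 1, 1 rose without acHKO_acute replicate 3, and 1 erythroid marker fell without GFP_acute replicate 1 or 2. No cell cycle gene reached a mean of 1 TPM in the acute fit, so that list was not tested.

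In all, 4058 of 9963 genes changed in the acute comparison, 591 higher and 3467 lower (85.4% lower). The split depended on the scaling: after median-ratio rescaling 1391 were higher and 2730 lower (66.2%), without mitochondrially encoded genes 1148 and 835 (42.1%), and over coding genes 1318 and 496 (27.3%). The authors' deposited table held 3522 higher and 3457 lower genes (49.5%), and 3202 of the 4053 limma calls listed there were called in the same direction, with 0 opposite. With camera 11 of 38 lists changed, 8 higher and 3 lower; with an estimated correlation 0 changed (1 at an unadjusted p under 0.05), and fry called 1. Leaving out a GFP library, replicate 2, raised the count of changed lists to 17, as did leaving out acHKO_acute replicate 2.

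The acute effect was also set against the HKO effect at 1 month in a test of their difference. It differed for 766 genes, 113 more positive and 653 more negative in the acute model (767 and 716 after median-ratio rescaling). The effect on 23 of 25 cell cycle genes was more negative in the acute model (24 adjusted over the list alone; camera adjusted p = 8.468e-27, estimated correlation adjusted p = 0.2627). As mean log2(TPM + 1) per library, cell cycle genes measured 0.18 to 0.25 with GFP and 0.26 to 0.36 with iCre. At 1 month they measured 0.22 and 0.46 in controls and 1.86 and 2.09 in HKO libraries. The difference thus reflects the rise at 1 month and not a fall in the acute model. The effect was also more negative for 5 of 16 fetal liver and oncofetal genes (8 adjusted over the list alone, camera adjusted p = 6.012e-05, estimated correlation adjusted p = 0.1556). Of 16 circadian clock genes 2 were more positive (2 adjusted over the list alone; camera adjusted p = 2.052e-04, estimated correlation adjusted p = 0.3536), as were 2 of 13 mitochondrially encoded genes (9 adjusted over the list alone; camera adjusted p = 3.147e-14, estimated correlation adjusted p = 0.3536). After median-ratio rescaling the fetal count was 8 and the mitochondrial count 6. The clock list did not pass camera after median-ratio rescaling (adjusted p = 0.05577). Model, age and library series differ together between these libraries, so a difference cannot be assigned to one of them. Without HKO_1m replicate 1 the count of 766 was 2127 and without GFP_acute replicate 1 it was 1392, while it was 384 without control_1m replicate 1, 505 without control_1m replicate 2, 365 without HKO_1m replicate 2 and 469 without acHKO_acute replicate 1.

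Some genes changed in all 3 comparisons. Of 9748 genes tested throughout, 77 were higher in each (1.2 would be shared by independent lists) and 27 lower in each (1.34). Those higher include Gsta1, Gsta2, Gstm2, Gstm3 and Gstp3, the lipid genes Cd36 and Cidec, Cd74, Lgals1, Tff3, Trib3 and Ugdh. Those lower include Crp, Itih4, Rpl29, Fkbp5, Ugt2a3 and Upp2. These examples were chosen after their values were seen. Across genes the acute fold changes had r = 0.427 with those at 1 month and r = 0.333 with those at P10, over genes that are not independent replicates. The acute and 1 month comparisons shared 124 higher genes (15 for independent lists) and 114 lower genes (77.1), and had 40 in opposite directions (109.3).

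Transcript usage was compared because SRSF1 regulates splice site choice. In the acute knockout 1213 of 3415 genes (35.5%) changed usage, against 25 of 4265 at P10 and 10 of 4265 at 1 month. A transcript of the phosphatase gene Dusp3, Dusp3-202, made up 82.4% of its gene's TPM in the acute knockouts and was listed at 0 in the controls. Mindy3-201 fell from 90.9% to 22.0%, Xpot-203 from 78.8% to 23.4%, and Tlk2-207, annotated as a target of nonsense-mediated decay, rose from 7.42% to 64.5%. Jmjd8-205 rose from 0.886% to 66.8 ± 57.6% (SD, n = 3), and Arap1 changed by 60.2 percentage points. Of 10 SR protein genes tested 4 changed usage, close to the 35.5% of other genes (one-sided Fisher p = 0.5003). Of 28 other splicing regulators 20 did, against 35.2% (one-sided Fisher p = 1.117e-04); these tests were added after the data were seen and do not match genes for abundance. Among the SR protein genes Tra2a-202, annotated for nonsense-mediated decay, rose from 46.6% to 87.2%, and the intron-retaining Srsf5-212 and Srsf6-204 rose from 21.4% to 41.3% and from 15.2% to 37.3%. Srsf6-203 fell from 77.4% to 47.8%, and Srsf11 changed as well, while Srsf1, Srsf2, Srsf3, Srsf4, Srsf10 and Tra2b did not pass. Of 10 tested genes linked to SRSF1 in the literature 5 passed (35.5% of other genes, Fisher p = 0.2598): Mknk2-201 rose from 23.7% to 42.8% and Tial1-214 from 10.2% to 40.3%, and Ptpmt1, Sdc1 and Slc39a14 changed too, while Bcl2l1, Insr, Numb, Rps6kb1 and Srsf1 did not pass. Over all genes called, 246 retained-intron transcripts gained at least 10 points and 61 lost as many, against 739 and 1024 protein-coding transcripts.

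At P10 Zfp949-203 rose from 8.71% to 84.1% of its gene, Rbp2-202 from 0 to 60.6%, Gsn-205 from 9.07% to 63.6%, Snd1-202 from 3.34% to 52.7% and Arhgef2-219 from 7.63% to 56.7%, while Hyi-205 fell from 44.1% to 0.243%. Hyi-205 is annotated as a polymorphic pseudogene. Since the HKO controls are not described as floxed, a sequence difference between the mouse lines could give such switches at either age. This was not tested, so they cannot be assigned to loss of SRSF1 alone. At 1 month Snd1-202 rose from 0 to 33.4% and Egfr-202 fell from 62.2% to 37.4%. TPM are corrected for length, so few reads can give Snd1-202, at 110 bases, a large share. Mup1, Mup2 and Il11ra1 changed by 54.3, 25.1 and 27.2 points. Both ages called 4 genes (0.06 for independent lists): Snd1, Il11ra1, Tprkb and 1600014C10Rik. The acute model shared 7 called genes with P10 (4.73 for independent lists, one-sided Fisher p = 0.1527) and 3 with 1 month (3.63, p = 0.767). Snd1 and Tprkb were among the shared genes at both ages. Both acute groups are floxed, so a line difference cannot give their acute calls. The overlaps did not pass the Fisher test, so the HKO calls of these genes remain unassigned. Srsf1 itself was not called in any comparison. At an unadjusted p under 0.05 there were 302 genes at P10 and 272 at 1 month. In simulated data the usage test gave 12 false calls in the P10 design and 11 in that at 1 month, without a minimum share difference. Those simulations changed 100 genes at each size, which loosens the adjusted threshold. The false calls therefore cannot be set directly against the counts of HKO calls. Without control_P10 replicate 1, control_P10 replicate 2 or HKO_P10 replicate 2 the P10 count was 8, 11 or 9, and without HKO_1m replicate 2 the 1 month count was 23.

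The control libraries give the developmental background, as 1 month minus P10. All 26 cell cycle genes were lower at 1 month (26 adjusted over the list alone; camera adjusted p = 1.625e-16, estimated correlation adjusted p = 0.4083), as were 14 of 16 fetal liver and oncofetal genes (14 adjusted over the list alone; camera adjusted p = 1.391e-08, estimated correlation adjusted p = 0.07251). Of 17 male-biased liver genes 15 were higher (16 adjusted over the list alone; camera adjusted p = 4.59e-27, estimated correlation adjusted p = 0.2755), and of 30 cytochrome P450 and drug metabolism genes 19 were higher and 1 lower (19 and 1 adjusted over the list alone; camera adjusted p = 7.717e-18, estimated correlation adjusted p = 0.4083). Afp, the fetal serum protein, chosen after its values were seen, fell from 1288 ± 255.6 to 0.358 ± 0.181 TPM (SD, n = 2). Afp measured 7299 ± 1698 TPM in the HKO libraries at P10 (relative log2 fold change against control 2.24, SE 0.26, adjusted p = 1.574e-04) and 0.931 ± 0.0713 TPM at 1 month (adjusted p = 0.334). In all, 5194 genes changed, 714 higher and 4480 lower, with 3004 higher and 2197 lower after median-ratio rescaling. The count was 3214 without control_P10 replicate 1 and 3055 without control_P10 replicate 2.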

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

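The tests of mitochondrial transcripts, miRNA genes, mRNA per cell, power, pseudocount, macrophages and regrowth were chosen after the results were seen. The test of intron-containing RNA, the other splits of the libraries and the differences between comparisons were set beforehand.

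The HKO effect differed between P10 and 1 month for 329 genes by the test of the difference itself, with 203 to 1688 genes when 1 library was left out. The highest count, 1688, came without HKO_1m replicate 2, and 203 and 207 came without control_P10 replicates 1 and 2. As log2 differences (effect at 1 month minus effect at P10, deposited TPM), the largest were 6.81 for Sult2a2 (SE 0.79, limma adjusted p = 0.001014), 5.21 for H19 (SE 0.62, adjusted p = 0.001238), 5.001 for Cyp3a41a, 4.50 for Sult2a1 and 4.03 for Prok1. In the other direction they were -8.29 for Hamp (SE 0.50, adjusted p = 3.355e-05), -4.76 for Mt2, -4.22 for Lcn2, -4.22 for Rgs16 and -4.16 for Gpt2. Without HKO_P10 replicate 2, whose Xist and Y-linked RNA are those of a female among males, Sult2a2 and Cyp3a41a still passed in the same direction. H19 measured 5445 TPM in control and 3974 TPM in HKO libraries at P10, and 0.192 and 37.2 TPM at 1 month.

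The acute effect differed from the HKO effect at 1 month for 766 genes by the test of the difference, with 365 to 2127 genes when 1 library was left out. It was 2127 without HKO_1m replicate 1, 1392 without GFP_acute replicate 1, 384 without control_1m replicate 1, 505 without control_1m replicate 2, 365 without HKO_1m replicate 2 and 469 without acHKO_acute replicate 1. The largest log2 differences (acute minus 1 month) were 5.43 for Rgs16 (SE 0.61, adjusted p = 7.938e-05), 3.86 for the clock gene Ciart (SE 0.52, adjusted p = 4.546e-04), 3.60 for Ddit4, 3.22 for the clock-controlled gene Dbp and 3.17 for Mup8. In the other direction they were -5.32 for Ly6d (SE 0.21, adjusted p = 2.509e-09), -5.24 for Onecut1, -4.75 for Nrep, -4.73 for H19 and -4.41 for Socs2. The time of day at sampling is not known, so differences in clock genes and other genes with a daily rhythm cannot be assigned to the knockouts alone.

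Of the 4058 genes changed in the acute knockout 85.4% were lower. After mitochondrially encoded genes were left out and TPM rescaled the share was 42.1%, and after median-ratio rescaling it was 66.2%. Leaving out a class whose share grew raises all other genes in the knockouts relative to the controls, whatever made it grow. The 42.1% therefore shows a dependence on the scaling and cannot decide what caused the excess of lower genes. The miRNA gene class does not account for it: its share changed by -2.93 percentage points of TPM (SE 3.42), where a rise of 17.1 would have been needed. Other classes of short RNA were not examined. A loss of nuclear-encoded mRNA per cell, with mitochondrially encoded genes left behind (median relative log2 fold change 1.68), cannot be told apart from a rise of mitochondrial transcripts, since TPM hold no amounts per cell. No biological explanation was tested beyond that.

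Changed transcript usage was called in 1213 genes in the acute knockout, against 25 and 10 in the HKO comparisons. For intron-containing or unspliced RNA, 30.3% of genes whose tested transcripts were all protein-coding were called (502 of 1657), against 40.4% of the others (711 of 1758). Calls were thus not confined to genes with other transcript classes tested. Intron reads can be assigned to coding transcripts too, so this does not exclude that cause. Retained-intron transcripts took 3.13 ± 0.63% of coding-gene TPM in acute knockouts and 1.94 ± 0.4% in controls (SD, n = 3, exact permutation p = 0.1, the smallest possible). A pseudocount acting on generally lower TPM is argued against by the 1194 genes called with a pseudocount of 0.1. Lower power in the HKO comparisons may account for part of the gap: transcripts that moved by at least 10 points in the acute model went the same way in 81.7% of cases at P10 and 65.3% at 1 month (mean 73.5%), by a median of 4.33 and 2.12 points against 17.9 and 18.0 in the acute model. How much of the gap power explains is not settled. Simulated changes of log2 2 were recovered in 51 and 60 of 100 genes against 75 in the acute model (17 and 13 against 38 at log2 1). These rates differ by less than the counts of calls do. However, the simulations changed 100 genes at each size, and many changed genes loosen the adjusted threshold. Of the HKO calls also tested in the acute model, 7 were shared at P10 (4.73 for independent lists, Fisher p = 0.1527) and 3 at 1 month (3.63, p = 0.767). With 13 and 10 such calls the overlap cannot show whether usage changes are shared.

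All 26 cell cycle genes were higher in HKO hepatocytes at 1 month, where macrophage markers were higher too. Macrophages in the preparation cannot be told apart from a change in hepatocytes: relative to all genes, cell cycle genes were higher by a median log2 of 0.20 (quartiles 0.07 to 0.31) in the HKO library richer in macrophage markers (1.58), but this sets 1 library against 1. Those libraries also held 50.3% and 35.5% of TPM in mitochondrially encoded transcripts, and Lyz2 reached 25.9 TPM in the richer of them. Regrowth of hepatocytes that kept Srsf1 cannot be told apart from division of knockout hepatocytes: Srsf1's log2 fold change at 1 month minus that at P10 was -0.52 on the deposited TPM (SE 0.32, limma adjusted p = 0.4336), -0.26 relative to the median gene and -0.33 after median-ratio rescaling, and bulk TPM do not say which cells divide. Other dividing cell types remain open.

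The 6 acute libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4058 genes and 1 of the 10 splits gave as many; the highest of the others gave 0. For transcript usage the real split gave 1213 genes, 1 of the 10 splits gave as many, and the highest other gave 1. Every other split mixes knockouts and controls, so the knockout difference adds to the spread within its groups and lowers its calls. The gene and usage counts of the other splits therefore do not measure what unchanged libraries would give. For gene lists the real split gave 11, and 7 of the 10 splits gave at least as many, the highest other 18, so with the preset correlation camera called lists in splits that mix both groups.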

How the results depend on the processing

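Tests added after the data were seen are the rescalings over nuclear-encoded protein-coding genes and without mitochondrially encoded genes, and the separate usage fits; the other alternatives were set beforehand. Of the genes named for a comparison, 174 results were recomputed under 2847 alternatives: 2443 kept their direction and side of the threshold, 403 kept their direction and no longer passed (139 of them with 1 library left out), and 1 reversed, Taldo1 in the acute knockout at 0.06 over coding genes. The gene counts moved by over 1.5 times as follows, and unless the alternative tests fewer genes or sets a minimum change, the cause was not tested. At P10, 1488 genes became 932 with a pseudocount of 0.1, 2236 with no filter, 805 with at least 5 TPM, 2541 with quantile normalization, 2328 without mitochondrially encoded and the 20 most abundant genes, 4599 over coding genes, 3582 without mitochondrially encoded genes, 5007 in a separate fit, 729 with a log2 fold change of at least 1, and 4845 in the authors' deposited table. At 1 month, 805 became 391 with no filter, 1687 with median-ratio rescaling, 1325 with quantile normalization, 4184 without mitochondrially encoded and the 20 most abundant genes, 4107 over coding genes, 2856 without mitochondrially encoded genes, 536 with a log2 fold change of at least 1, and 2454 in the deposited table. In the acute knockout 4058 became 2658 with at least 5 TPM, 1814 over coding genes, 1983 without mitochondrially encoded genes, 1122 with a log2 fold change of at least 1, and 6979 in the deposited table. The difference between ages, 329, became 530 with median-ratio, 766 with quantile, 1149 without mitochondrially encoded and the 20 most abundant genes, 507 with robust variances and 733 over coding genes. The difference between acute and 1 month, 766, became 464 with at least 5 TPM, 1483 with median-ratio, 1686 with quantile, 1412 without mitochondrially encoded and the 20 most abundant genes, and 1164 without mitochondrially encoded genes. In controls 5194 became 2634 with at least 5 TPM and 8849 without mitochondrially encoded and the 20 most abundant genes. Srsf1 at P10 passed with median-ratio rescaling (-1.01), over coding genes (-0.71) and in the deposited table (-1.07, adjusted p = 6.324e-12). Lists called fell to 0, 0 and 0 with an estimated correlation and to 13, 5 and 1 with fry at P10, 1 month and acute, and over coding genes they were 23 at 1 month and 19 in the acute knockout. Usage calls at P10 became 78 in a separate fit, and at 1 month 17 with a pseudocount of 0.1, 25 with a share minimum of 1% and 4 in a separate fit. The correlations of the deposited fold changes were 0.416 (P10 and 1 month) and 0.367 (1 month and acute).

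With 1 library left out, which in the HKO groups leaves a lone library assumed to vary like the other groups, genes changed ranged from 562 to 896 at P10, 613 to 1344 at 1 month and 2801 to 5188 in the acute knockout. They ranged from 203 to 1688 for the difference between ages, 365 to 2127 for acute against 1 month, and 3055 to 4638 in controls. On the deposited TPM, not relative to the median gene, Srsf1 ranged from -0.91 to -0.57, -1.37 to -1.15 and -2.58 to -2.12 (log2; -0.74, -1.26 and -2.29 with all libraries), lists from 20 to 27, 22 to 30 and 11 to 17, and usage from 8 to 26, 9 to 23 and 882 to 1177, each at P10, 1 month and acute. The correlations ranged from 0.35 to 0.378, 0.364 to 0.469 and, for P10 and acute, 0.274 to 0.36. The depth per library is unknown, so what depth limits cannot be given.

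Whether replicate numbers pair the samples is not settled. Same-numbered libraries deviated together with r = 0.007 at P10, 0.283 at 1 month, and -0.039, 0.27 and 0.184 in the acute model. With 2 libraries per group, crossed numbers give the same r with the opposite sign, so the HKO values cannot decide this. Crossed numbers in the acute model gave r from -0.265 to 0.092. With a replicate block the gene counts were 2936 at P10, 1503 at 1 month, 3208 in the acute knockout and 981 for the difference between ages, usage calls were 74, 46 and 1092, and Srsf1 at P10 passed with the same fold change (-0.74). In the acute model libraries 2 and 3 correlated best with their own number and library 1 did not.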

Other observations

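The gene groups in this part were tested with lists set before the data were examined, and the test of growth hormone response genes was written before their values were seen.

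Further gene groups moved in the HKO libraries. At P10, 9 of 27 type I interferon response genes rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 7.511e-04, estimated correlation adjusted p = 0.7504), with 4 higher and 1 lower after median-ratio rescaling. The interferon count was 3 without either control library and 4 without HKO_P10 replicate 2. Of 23 cell death and injury genes 11 rose and 1 fell at P10 (13 and 2 adjusted over the list alone; camera adjusted p = 7.511e-04, estimated correlation adjusted p = 0.7504). At 1 month 5 of 13 genes of the imprinted gene growth network rose (7 adjusted over the list alone; camera adjusted p = 2.471e-04, estimated correlation adjusted p = 0.235), with 2 higher and 1 lower without control_1m replicate 1, 3 higher without control_1m replicate 2, and 5 higher and 1 lower after median-ratio rescaling. The imprinted list did not pass camera over coding genes (adjusted p = 0.5424) or without mitochondrially encoded genes in the scaling (0.09244). Of 17 male-biased liver genes 8 fell and 2 rose at 1 month (3 and 8 adjusted over the list alone; camera adjusted p = 0.00449, estimated correlation adjusted p = 0.6992), while without HKO_1m replicates 1 and 2 the counts lower were 4 and 3. The male-biased list did not pass camera after median-ratio rescaling (adjusted p = 0.1342) or under quantile normalization (0.5366), nor without control_1m replicate 1 or HKO_1m replicate 2. In the acute knockout 15 of 24 acute phase genes fell and 1 rose (2 and 15 adjusted over the list alone; camera adjusted p = 0.04374, estimated correlation adjusted p = 0.9358), and 10 fell and 2 rose after median-ratio rescaling, under which the list did not pass camera (adjusted p = 0.2582), nor under quantile normalization (0.1782) or without GFP_acute replicate 1 or 3.

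A hypothesis was that growth hormone signalling through STAT5 was lower in the acute knockout, since this pathway drives Igf1 and male-biased liver genes. Of 7 response genes listed before their values were seen, 6 were tested, and their median relative log2 fold change was -1.66. Onecut1 (-3.01, SE 0.31), Igfals (-2.20, SE 0.28), Socs3 (-1.99, SE 0.21) and Igf1 (-1.34, SE 0.30) were lower on both the deposited and the median-ratio scale, with limma adjusted p of 7.893e-07, 4.324e-06, 7.627e-07 and 4.485e-04. Serpina3k (-0.77) and the growth hormone receptor gene Ghr (-0.30) did not pass after median-ratio rescaling. Of 19 male-biased liver genes 11 fell and 2 rose in the acute knockout (3 and 13 adjusted over the list alone), and whether the list passed camera depended on the scaling. It did not on the deposited TPM (adjusted p = 0.08073, estimated correlation adjusted p = 0.9358) or after median-ratio rescaling (0.3826), and it passed over coding genes (1.678e-09) and without mitochondrially encoded genes (0.003167). On the deposited TPM it stayed above 0.05 without GFP_acute replicate 1 or 3 and passed without any of the other libraries. The values are consistent with lower growth hormone signalling, which was not measured, and a general fall of hepatocyte products could give the same values.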
